A study of Drosophila melanogaster with 10 samples.

How the data were processed

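The series holds 10 samples of Drosophila melanogaster S2 cells: ChIP samples for Mod(mdg4)2.2, Su(Hw), dCTCF and CP190, and an input, each from cells kept with water (control) or with 3AB. Per the labels, 3AB was added from a 120 mM stock to 12 mM for 16 h, and cells were fixed with 1% formaldehyde for 10 min. Each of the 8 ChIP samples came with a signal track and a peak list, and the 2 input samples were not analysed here as samples of their own. The group of every sample was taken from its labels. There was 1 library per protein and condition.

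Reads were aligned with Bowtie 0.12.5, per the submitters' processing notes, and peaks were called per sample with MACS 1.4 against an input, per the file headers. The headers give a p cutoff of 1e-05, a band width of 300 bp, and regional background windows of 1000 and 10000 bp. They give a limit of 4 duplicate tags per position in both CP190 libraries and the dCTCF control and of 3 in the other ChIP libraries. Tags per peak are deposited as counts, which the caller made. The deposited score of a peak is taken here to be minus 10 times the log10 of its p; the title of that column was lost, and its place and its minimum near 50 fit the p cutoff. This authors' score was used only to describe and rank peaks within a list. The fold enrichment over the input, a ratio, and the FDR, in percent, are the authors' own values per peak. Peaks with an FDR above 5% made up from 11.2% of the list, for dCTCF with 3AB, to 36.1%, for the Mod(mdg4)2.2 control, and all deposited peaks were kept. The genome build is not given in the sources used here. Chromosome names follow release 5, a genome or annotation of that release was not used here, and the gene table at hand is of release 6, so regions carry no gene names. For that reason the planned gene lists, genomic locations and motif searches were not run.

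The deposited signal tracks give coverage in 100 bp bins, not normalised to depth. In the CP190, dCTCF and Mod(mdg4)2.2 tracks the total signal divided by the fragment length of the headers was between 0.995 and 0.997 times the filtered tags, as it would be with tags extended to that length. Fragment lengths in control and with 3AB were 87 bp and 115 bp for CP190, 98 bp and 91 bp for dCTCF and 85 bp and 94 bp for Mod(mdg4)2.2. For Su(Hw), with 150 bp and 146 bp, the ratio was 1.64 and 1.63, so the number of tags behind these tracks is not known and no tag ratio is given. The headers give 8260000 and 8013013 Su(Hw) tags before filtering, and whether these tracks keep duplicate tags was not tested. Reads were 50 bp long for Su(Hw) and 36 bp for the others. The peaks held 52.6% in control and 40.6% with 3AB for CP190, 36.3% in control and 23.6% with 3AB for dCTCF, 54.0% in control and 51.8% with 3AB for Su(Hw), and 48.1% in control and 48.6% with 3AB for Mod(mdg4)2.2, as shares of the filtered tags.

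Each track was scaled to the same mean over all bins of arms 2L, 2R, 3L, 3R, 4 and X, and peaks elsewhere were left out of signal comparisons. Control and 3AB peaks of a protein that shared at least 1 bp were merged, and the mean signal of each region gave log2((3AB + 1)/(control + 1)), where 1 is the arm mean. This scale understates the change of weak regions. Medians carry order-statistic intervals, shares Wilson intervals, and differences of class medians intervals from 1000 bootstrap resamples of the sites. Tag ratios of named regions use the signal divided by the fragment length, relative to the filtered tags, with exact binomial intervals. PCR copies are not independent molecules, and intervals cover counting error or the spread over regions only. Chance co-occupancy came from 1000 circular shifts along each arm. Classes of control peaks were compared with 10000 random sets of peaks of the same protein, of equal size and matched on deciles of control signal. Background windows had the width of a region, lay 5 kb from it and met no peak of the 8 lists. The flanking background of a region was the mean of bins 500 bp to 5 kb from its edges and more than 200 bp from every peak, where at least 10 such bins were present.

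Named regions were chosen by a rule fixed before the data were examined. Per protein it took the 6 regions with the lowest and the 6 with the highest log2 change among the upper 50% of merged regions by signal in the higher condition, the 6 control peaks with the highest score, and the 3 highest-scoring peaks of each condition alone; a selection of these is printed. The score has a ceiling, which 11.5% of the peaks reached for dCTCF with 3AB and 35.4% for the Su(Hw) control, so it does not rank the strongest peaks, and the 6 highest-scoring control peaks are not used here. Alternatives fixed at the same time were a 50% reciprocal overlap, peak centres within 250 bp, the upper 50% of each list by score, equal numbers of top peaks, tracks without scaling, scaling outside all peaks, a pseudocount of 0.25 or 4, the highest bin, the upper 50% of regions by mean signal of both tracks, and control peaks alone. Signal relative to the flanking background, regions widened by 200 bp, regions without arm 4, the classes of the proteins other than CP190, and the differences between class medians were added after the data had been seen.

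Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlap counts were checked against bedtools and were equal for the 4 proteins at 1 bp and at 50% reciprocal overlap. The signal step was tested on simulated data drawn from the control tracks, with sets of 50 regions changed by known factors. The changed regions were taken from merged regions with control signal at or above the median, so changes at weaker regions were not tested. The simulated data hold counting noise alone, not the spread between libraries. Of the unchanged regions, 0 of 10694 passed a log2 change of 1 in either direction for CP190, 0 of 8306 for dCTCF and 0 of 8397 for Mod(mdg4)2.2. Of 50 regions lowered 4-fold, 50 passed −1 for CP190, 50 for dCTCF and 50 for Mod(mdg4)2.2. Of 50 lowered 2-fold, 3, 6 and 8 passed, with medians of −0.87, −0.86 and −0.88. Unchanged regions scattered around the simulated value with an SD of 0.095 for CP190, 0.16 for dCTCF and 0.15 for Mod(mdg4)2.2. Su(Hw) was not simulated, since its tag number is not known.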

Results

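Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 4 Drosophila insulator proteins in S2 cells, a cultured line of embryonic origin with features of blood cells, with or without 3AB, an inhibitor of poly(ADP-ribose) polymerase (PARP). The proteins were CP190, a BTB-domain zinc finger protein found at most insulator classes, the sequence-specific zinc finger proteins dCTCF and Su(Hw), and Mod(mdg4)2.2, a BTB-domain partner of Su(Hw). Cells received water or 3AB at a final dose of 12 mM for 16 h. Each protein was profiled in 1 control and 1 3AB library, so the 8 libraries held no replicates, no test between conditions was possible and no difference below has a replicate check. The question the design addressed was which insulator sites gained or lost protein when PARP activity was inhibited. After duplicate filtering the libraries held 12115560 tags for CP190 in control and 12205439 with 3AB, 6495352 and 6400607 for dCTCF, 5205256 and 5018999 for Su(Hw), and 5613953 and 5610807 for Mod(mdg4)2.2. All intervals are 95% intervals that cover counting error, or the spread over regions, within these libraries only. Regions are named by chromosome arm and position in the coordinates of the deposited files, which carry release 5 style chromosome names without a stated build, and signal is given in multiples of each library's mean over the 6 major arms.

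The CP190 list was shorter with 3AB and the Mod(mdg4)2.2 list longer, and dCTCF had many peaks in 1 condition alone in both directions. The share of control peaks that overlapped a 3AB peak was highest for Su(Hw), with an interval overlapping that of Mod(mdg4)2.2. The reverse share was highest for CP190. The control lists held 10699 CP190, 6215 dCTCF, 5845 Su(Hw) and 6938 Mod(mdg4)2.2 peaks, and the 3AB lists 9050, 6878, 5733 and 8001. Of the control peaks, 79.5% of CP190 (Wilson interval 78.7% to 80.3%), 69.2% of dCTCF (68.0% to 70.3%), 89.5% of Su(Hw) (88.6% to 90.2%) and 89.3% of Mod(mdg4)2.2 (88.5% to 90.0%) overlapped a 3AB peak of the same protein. In the reverse direction, 94.5% of the CP190 peaks found with 3AB were also present in control (94.0% to 94.9%), against 65.3% for dCTCF (64.2% to 66.4%), 91.7% for Su(Hw) (90.9% to 92.4%) and 76.9% for Mod(mdg4)2.2 (76.0% to 77.8%). Peaks found in control alone numbered 2192 for CP190, 1914 for dCTCF, 616 for Su(Hw) and 745 for Mod(mdg4)2.2, and peaks found with 3AB alone numbered 499, 2387, 477 and 1846. Many of these were weak calls. An authors' FDR above 5% was held by 79.1%, 70.1%, 94.0% and 88.5% of the control-only peaks of these proteins, and by 75.2%, 24.5%, 96.2% and 71.1% of the 3AB-only peaks. In the whole dCTCF lists that share was 35.35% in control and 11.2% with 3AB. The low share of dCTCF peaks called with 3AB alone is therefore no sign of stronger peaks.

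**Figure D1:**
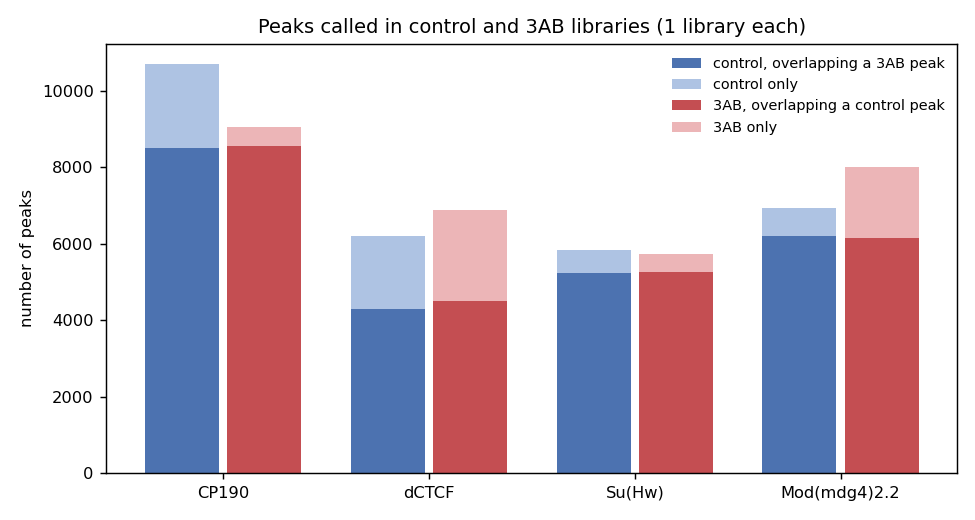
Number of peaks (y axis) in the control and 3AB list of each protein, 1 library per bar, split into peaks that overlapped a peak of the other condition by at least 1 bp (dark) and peaks that did not (pale). The pale part is largest for CP190 in control, with 2192 peaks, and for dCTCF with 3AB, with 2387.

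Peaks present in 1 condition alone scored lower than shared ones by the authors' own score. The median score of control-only CP190 peaks was 125, against 1894 for the retained ones, and the corresponding medians were 86.3 and 388 for dCTCF, 80.2 and 1967 for Su(Hw), and 89.0 and 671 for Mod(mdg4)2.2. Peaks found with 3AB alone had median scores of 73.8 for CP190, 65.9 for dCTCF, 72.05 for Su(Hw) and 90.35 for Mod(mdg4)2.2. The 3AB peaks shared with control had 878, 199, 1628 and 684. Retention was 39.8% in the 25% of the CP190 control list with the lowest score and 34.4% in that of dCTCF. The score has a ceiling. Of the 3315 CP190 control peaks that reached it 99.4% were retained (99.1% to 99.6%), and 19 were lost. All 1140 such dCTCF peaks were retained. The median 3AB signal at control-only regions was 1.28 for CP190, 1.54 for dCTCF, 1.6 for Su(Hw) and 1.48 for Mod(mdg4)2.2. The 95th percentile of same-width windows 5 kb away differed more between the tracks, at 1.44, 1.84, 0.925 and 0.975. Signal above that level was present with 3AB at 38.3% of the 2164 control-only CP190 regions, 30.1% of the 1900 dCTCF regions, 93.5% of the 615 Su(Hw) regions and 83.8% of the 740 Mod(mdg4)2.2 regions. In control, 93.8% of the 1842 Mod(mdg4)2.2 regions called with 3AB alone exceeded the level of their own track, 1.01, and 38.4% of the 2369 dCTCF regions called with 3AB alone exceeded 1.53. The shares of different proteins thus rest on different levels, and the difference was not tested.

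CP190 signal was lower with 3AB at most of its sites, in a library whose peaks held 40.6% of the filtered tags, against 52.6% in control. Whether this lower enrichment came from binding or from the library was not tested. Over the 10894 regions of the merged control and 3AB lists, the median log2 change was −0.28 (interval −0.29 to −0.28), with quartiles of −0.55 and −0.081, and 9069 regions (83.2%) had a value below 0. A log2 change of −1 or less was seen at 784 regions and of 1 or more at 0. Without scaling these numbers were 431 and 14, with scaling outside all peaks 1478 and 0, and with the highest bin 1823 and 17. In simulated libraries of the same depth with 10694 unchanged regions, 0 of these passed either limit, 50 of 50 regions lowered 4-fold passed, and 3 of 50 regions lowered 2-fold passed, because the pseudocount shrinks the log2 scale. The lowered regions all had control signal at or above the median, so these numbers do not hold for weaker regions. The simulation holds counting noise alone and gives no measure of the spread between separate libraries. The 6 strongest losses were discrete sites whose 3AB signal lay below 1.44, the 95th percentile of background windows beside control-only regions in that track: 2L from 15903004 to 15903561 (11.4 to 0.452, log2 −3.09), 2L from 20024187 to 20024828 (10.3 to 0.442, log2 −2.97), 3R from 12809994 to 12810334 (15.2 to 1.08, log2 −2.96), 2R from 20917114 to 20917530 (6.80 to 0.0660, log2 −2.87), 3L from 4464673 to 4465100 (12.7 to 1.00, log2 −2.77) and 2L from 7756838 to 7757428 (11.8 to 0.899, log2 −2.75). None of these 6 had a CP190 peak with 3AB. In tags, the ratio of 3AB to control was 0.0395 (0.0258 to 0.0579) at the first and 0.00881 (0.00181 to 0.0260) at the fourth. At the first of these sites, which overlapped control peaks of all 4 proteins, the log2 change was −0.00057 for Su(Hw) and −0.53 for Mod(mdg4)2.2, while dCTCF signal over the region was low in both tracks (0.641 and 0.0980). On 3L from 4464673 to 4465100, where control had peaks of Su(Hw) and Mod(mdg4)2.2, Su(Hw) changed by 0.0060 and Mod(mdg4)2.2 by −0.53. Background windows beside control-only regions had a 3AB median of 0.546. CP190 lay below it on 2L from 15903004 and 20024187 and 2R from 20917114. Without a control dCTCF peak, dCTCF fell on 2L from 20024187 (0.710 to 0.213) and 2R from 20917114 (0.612 to 0.155). It also fell on 3R from 12809994 (0.447 to 0.0168). It rose on 3L from 4464673 (0.127 to 0.238) and 2L from 7756838 (0.478 to 0.690). A dropout of fragments cannot be told apart from a loss of CP190 here.

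CP190 increases were small by comparison. Among the 50% of regions with the higher signal in either condition, the largest were on 3L from 5913738 to 5914551 (2.92 to 5.59, log2 0.75), 2L from 19003107 to 19003582 (2.63 to 4.43, log2 0.58), 3L from 17955219 to 17955935 (5.07 to 7.63, log2 0.51), 3R from 628815 to 629458 (2.89 to 4.48, log2 0.50), 2R from 7251687 to 7252820 (3.01 to 4.64, log2 0.49) and X from 15208203 to 15208947 (3.48 to 5.30, log2 0.49). The highest-scoring CP190 peak called with 3AB alone, on 2L from 484221 to 485145 (4.51 to 5.78, log2 0.30), already carried signal in control. The size of the CP190 change depended on the scaling: the median was −0.56 with the tracks scaled to the same mean outside all peaks, and 0.046 without any scaling, where the longer tag extension of the 3AB track (115 bp against 87 bp) raises its values.

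dCTCF signal was lower with 3AB at its strong sites, in a library whose peaks held 23.6% of the filtered tags, against 36.3% in control. Over 8506 regions the median log2 change was −0.22 (−0.24 to −0.21), with quartiles of −0.55 and 0.24. At the strongest 10% of the regions, 851 in number, the median was −0.62 (−0.65 to −0.60). A change of −1 or less was seen at 552 regions and of 1 or more at 105. Of the latter, 104 were called with 3AB alone, a choice that by itself favours higher values. The largest losses left reduced peaks in place: 3R from 92505 to 93178 (32.0 to 5.30, log2 −2.39), 3R from 10657852 to 10658423 (26.2 to 4.53, log2 −2.30), 3L from 11037800 to 11038831 (12.3 to 1.77, log2 −2.27), 3R from 9697813 to 9698457 (18.5 to 3.11, log2 −2.25), 3R from 13496930 to 13497516 (22.1 to 4.03, log2 −2.20) and 2L from 13732180 to 13732936 (29.9 to 6.14, log2 −2.12). All 6 were still called with 3AB. At the first of them, which held control peaks of all 4 proteins, CP190 changed by −1.94, Su(Hw) by −1.69 and Mod(mdg4)2.2 by −1.79, whereas the fourth was bound by dCTCF alone. The highest-scoring peaks lost from the list were on 3L from 22924896 to 22925621 (8.77 to 1.64, log2 −1.89), 3R from 6477943 to 6478421 (7.09 to 1.52, log2 −1.68) and 2L from 3131599 to 3132160 (5.08 to 2.20, log2 −0.93).

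The largest dCTCF increase among the 50% of regions with the higher signal in either condition was on 2L from 9964820 to 9966997 (3.12 to 12.9, log2 1.75). Its tag ratio was 4.10 (3.66 to 4.61). Among the 50% of regions with the higher signal in either condition, the next 5 were 3R from 16717248 to 16717547 (0.999 to 3.74, log2 1.24), 3R from 16895347 to 16895649 (0.927 to 3.11, log2 1.09), 3L from 5734829 to 5735323 (1.20 to 3.54, log2 1.05), 2R from 7251774 to 7252636 (1.51 to 4.08, log2 1.02) and 2L from 1061192 to 1062082 (1.26 to 3.38, log2 0.95), and none of these 5 had a control peak. The 2369 dCTCF regions called with 3AB alone had a median signal of 1.34 in control and 2.32 with 3AB, and 28.4% of these peaks overlapped a control CP190 peak (26.6% to 30.2%), against 81.5% of the retained dCTCF peaks (80.3% to 82.6%). Another selection took the 50% of regions with the higher mean of control and 3AB signal. There the median was −0.39 and 2 of 4253 regions passed 1. With scaling outside all peaks the median was −0.42, with 1051 regions at −1 or less and 19 at 1 or more. The duplicate filter kept up to 4 tags per position in control and up to 3 with 3AB.

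Over the merged regions, Su(Hw) had the median change closest to 0 of the 4 proteins. Its median log2 change over 6268 regions was −0.030 (−0.035 to −0.023), with quartiles of −0.21 and 0.092, and at the strongest 10%, 627 regions, it was 0.021 (0.0095 to 0.032). At control peaks alone the median was −0.047, against −0.037 for Mod(mdg4)2.2, and in the 50% of regions with the higher mean signal of both tracks −0.014 against −0.010. Without scaling the CP190 median (0.046) was closer to 0 than that of Su(Hw) (−0.12). This order thus depended on the regions and the scaling. Across regions, log2 signal in the 2 libraries correlated with a Pearson r of 0.957, the highest of the 4 proteins, against 0.883 for CP190, 0.854 for dCTCF and 0.875 for Mod(mdg4)2.2; regions are not independent replicates. A change of −1 or less was seen at 48 regions and of 1 or more at 0. These losses were led by 2R from 12988137 to 12989257 (9.35 to 2.27, log2 −1.66), 3R from 2151419 to 2152227 (7.45 to 1.79, log2 −1.60), 3R from 92499 to 93302 (6.97 to 1.70, log2 −1.56), 3R from 22175113 to 22175645 (7.55 to 2.12, log2 −1.45), 2L from 6394061 to 6394953 (10.1 to 3.21, log2 −1.40) and 3L from 18121044 to 18121744 (6.55 to 1.89, log2 −1.39). Each of these 6 held control peaks of CP190 and Mod(mdg4)2.2 as well. At the first, Mod(mdg4)2.2 changed by −2.95 and CP190 by −2.27, while dCTCF, without a peak there, had a signal of 0.397 in control and 0.441 with 3AB. Among the 50% of regions with the higher signal in either condition, the largest increases were on 3R from 12085969 to 12087051 (4.31 to 6.91, log2 0.57), 2L from 12520047 to 12520994 (4.63 to 7.00, log2 0.51), 3R from 25729541 to 25730606 (10.9 to 15.1, log2 0.43), 3R from 9763093 to 9764313 (5.60 to 7.84, log2 0.42), 2L from 19790865 to 19792502 (4.95 to 6.96, log2 0.42) and 3L from 17589710 to 17590624 (5.10 to 7.14, log2 0.41). The highest-scoring peak called with 3AB alone, on 3L from 626139 to 631430 (9.77 to 10.2, log2 0.054), had nearly equal signal in both tracks, although no control peak overlapped it. The number of tags behind the Su(Hw) tracks is not known, and whether they keep duplicate tags was not tested, which limits the comparison with the other proteins. With the highest bin of each region in place of the mean the Su(Hw) median was 0.0098.

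Mod(mdg4)2.2 was higher with 3AB at some sites and lower at others. The median log2 change over 8597 regions was 0.10 (0.088 to 0.12), with quartiles of −0.23 and 0.42. It was −0.037 at control peaks alone and −0.010 in the 50% of regions with the higher mean signal of both tracks, and 0.53 at the 1842 regions called with 3AB alone, where the call itself favours higher values. A change of −1 or less was seen at 275 regions and of 1 or more at 71, and without scaling these numbers were 199 and 185. The largest loss, on 2R from 12988279 to 12989167 (24.7 to 2.12, log2 −3.04), lay within the region with the largest Su(Hw) loss, and its tag ratio was 0.0860 (0.0692 to 0.106). Further losses were on 2R from 3894268 to 3894974 (9.53 to 0.770, log2 −2.57), 2L from 93873 to 94525 (12.1 to 2.03, log2 −2.11), 2L from 13730791 to 13731479 (10.7 to 1.81, log2 −2.06), X from 45921 to 46619 (15.3 to 2.94, log2 −2.05) and 3R from 22175087 to 22175528 (10.2 to 1.71, log2 −2.04). All 6 overlapped control peaks of CP190 and Su(Hw), and 1 of them, on 2L from 13730791 to 13731479, a dCTCF peak. Among the 50% of regions with the higher signal in either condition, the largest increases were on 2R from 18886034 to 18886763 (2.23 to 7.40, log2 1.38), 2L from 14133590 to 14134616 (5.10 to 14.2, log2 1.32), X from 5233922 to 5234393 (1.6 to 5.14, log2 1.24), 3R from 25318849 to 25319484 (1.74 to 5.45, log2 1.24), 2R from 3906260 to 3906829 (1.47 to 4.57, log2 1.17) and 3R from 26021129 to 26021755 (4.01 to 10.3, log2 1.17). All 6 overlapped a control CP190 peak and 5 a control dCTCF peak. CP190 changed at these 6 by between −0.048 and 0.30. A further peak called with 3AB alone, on 2L from 484092 to 485225 (3.84 to 9.09, log2 1.06), lay over the CP190 peak that was also called with 3AB alone.

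**Figure D2:**
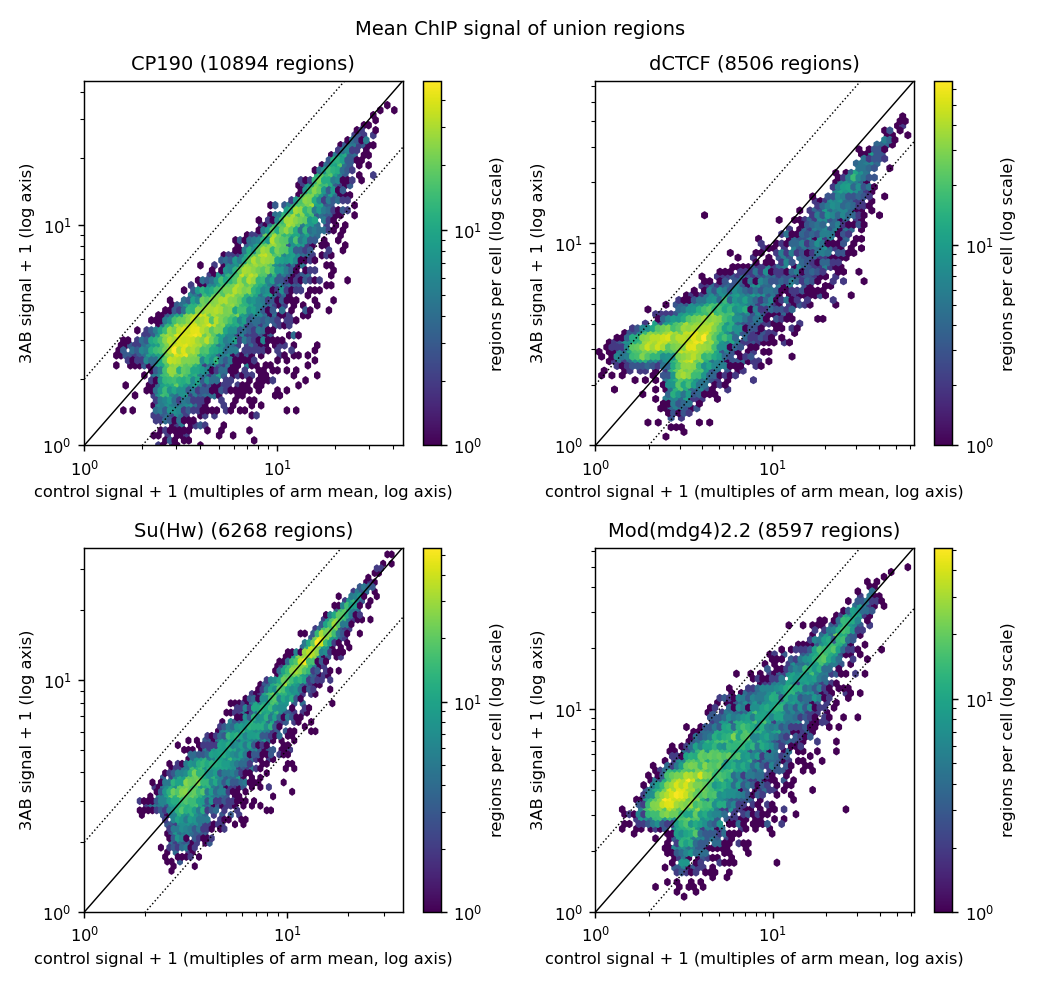
Mean signal of each region of the merged control and 3AB peak lists plus a pseudocount of 1, in control (x axis) and with 3AB (y axis), in multiples of the mean over the major arms on log axes, with colour giving the number of regions per cell. The solid line marks equal values and the dotted lines a log2 change of −1 and 1; CP190 has 784 regions on or below the lower line and 0 on or above the upper one, and Su(Hw) 48 and 0.

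The proteins shared many of their sites. With 3AB a lower share of each partner's peaks met a CP190 peak at 1 bp overlap, while a higher share of the shorter CP190 list met each partner. In control, 75% of dCTCF peaks (74.0% to 76.1%), 72.8% of Su(Hw) peaks (71.6% to 73.9%) and 76.4% of Mod(mdg4)2.2 peaks (75.4% to 77.4%) on the major arms overlapped a CP190 peak. With 3AB these shares were 62.4% (61.3% to 63.6%), 64.7% (63.5% to 65.9%) and 73.3% (72.3% to 74.3%). In numbers, 4632 dCTCF, 4241 Su(Hw) and 5278 Mod(mdg4)2.2 peaks met CP190 in control. With 3AB they numbered 4264, 3693 and 5844. Of the CP190 peaks, 42.9% met a dCTCF peak in control and 44.6% with 3AB, 43.0% and 43.4% a Su(Hw) peak, and 50.6% and 65.2% a Mod(mdg4)2.2 peak. After 1000 circular shifts of the peaks along each arm the mean share was between 9.97% and 14.9% for the 6 pairings. Mod(mdg4)2.2 overlapped 66.0% of the Su(Hw) peaks in control and 69.1% with 3AB, and 47.3% and 54.0% of the dCTCF peaks. Sites with all 4 proteins made up 1430 of 14064 merged sites in control (10.2%) and 1464 of 14210 with 3AB (10.3%). Co-occupancy with CP190 at 50% reciprocal overlap was 40.9% for Su(Hw) in control and 46.4% with 3AB, the opposite order, so the direction for Su(Hw) depended on the overlap rule.

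The median CP190 change was lowest at sites shared with Su(Hw) and Mod(mdg4)2.2 but without dCTCF, and closer to 0 at sites with dCTCF. The 2329 control CP190 peaks with Su(Hw) and Mod(mdg4)2.2 alone had a median log2 change of −0.54 (−0.56 to −0.52), and 74.6% of them were retained (72.8% to 76.4%). The 2649 CP190 peaks without any of the other proteins had a median of −0.38 (−0.39 to −0.36) and 70.6% were retained, and the 615 with Su(Hw) alone had −0.33 (−0.36 to −0.30) and 50.4%. This lowest retained share belonged to the class with the lowest control signal, 2.54 against 3.72 without the others, and at 50% reciprocal overlap these 2 shares were 69.6% and 70.6%. For peaks with dCTCF the median was −0.25 with dCTCF alone (1815 peaks, 87.5% retained), −0.17 with dCTCF and Mod(mdg4)2.2 (1117 peaks, 92.0%), −0.13 with dCTCF and Su(Hw) (171 peaks, 92.4%) and −0.24 with all 3 (1460 peaks, 97.7%). The 480 peaks with Mod(mdg4)2.2 alone had a median of −0.22. Drawn at 50% reciprocal overlap, that class had −0.40, below the −0.37 of peaks without the others. With scaling outside all peaks the medians were −0.80 with Su(Hw) and Mod(mdg4)2.2, −0.63 without the others and −0.57 with Su(Hw) alone. For dCTCF classes they were −0.55 with dCTCF alone, −0.48 with dCTCF and Mod(mdg4)2.2, −0.41 with dCTCF and Su(Hw) and −0.57 with all 3, so the last did not differ from Su(Hw) alone at 2 decimals. Among 10000 random sets of CP190 peaks of the same size and control signal, the median of the Su(Hw) and Mod(mdg4)2.2 class lay at the 0th percentile, where the middle 95% of sets ran from −0.35 to −0.33, that of peaks without the others also at the 0th, and those of each dCTCF class and of Mod(mdg4)2.2 alone at the 100th. The class with Su(Hw) alone lay at percentile 12.3. These percentiles describe the 2 CP190 libraries and not the conditions. In the CP190 library with 3AB the background was also less even, with 20.4% of windows outside peaks under 0.5 times their flanking level against 13.2% in control.

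The same classes, drawn up for the other proteins after the data had been seen, gave different orders. Mod(mdg4)2.2 was higher with 3AB at its 1140 control peaks with CP190 and dCTCF but without Su(Hw), with a median of 0.31 (0.29 to 0.33), and at the 1450 peaks with all 3 others, with 0.094 (0.075 to 0.12). It was lower at the 2213 peaks with CP190 and Su(Hw), with −0.23 (−0.25 to −0.20), and at the 346 with Su(Hw) alone, with −0.40 (−0.44 to −0.34), of which 59.0% were retained. The 964 peaks without any of the others were also lower, with −0.20 (−0.24 to −0.18). Of the 1842 Mod(mdg4)2.2 peaks called with 3AB alone on the major arms, 71.7% overlapped a control CP190 peak, 56.6% a dCTCF peak and 16.4% a Su(Hw) peak. Among the 740 control-only peaks these shares were 49.1%, 8.38% and 53.4%, and among the 6166 retained peaks 79.7%, 46.2% and 59.3%. Control-only peaks thus had a lower share of each partner than retained ones, Su(Hw) included. dCTCF was lowest at its 1170 peaks without the other proteins, with a median of −0.62 (−0.65 to −0.59) and 50.6% retained. Over the 4632 peaks with CP190 the median was −0.39 and 75.2% were retained. The 264 peaks with Mod(mdg4)2.2 alone had −0.18 and 51.1%, and the 46 with Su(Hw) alone −0.59 (−0.78 to −0.42) and 54.3%. Median control signal in these classes was, in that order, 3.05, 3.61, 2.64 and 3.05. All classes were drawn on control peaks, a choice that by itself favours lower values. Su(Hw) medians lay between −0.17, at the 1245 peaks without the others, and 0.021, at the 1423 peaks with all 3 others.

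**Figure D3:**
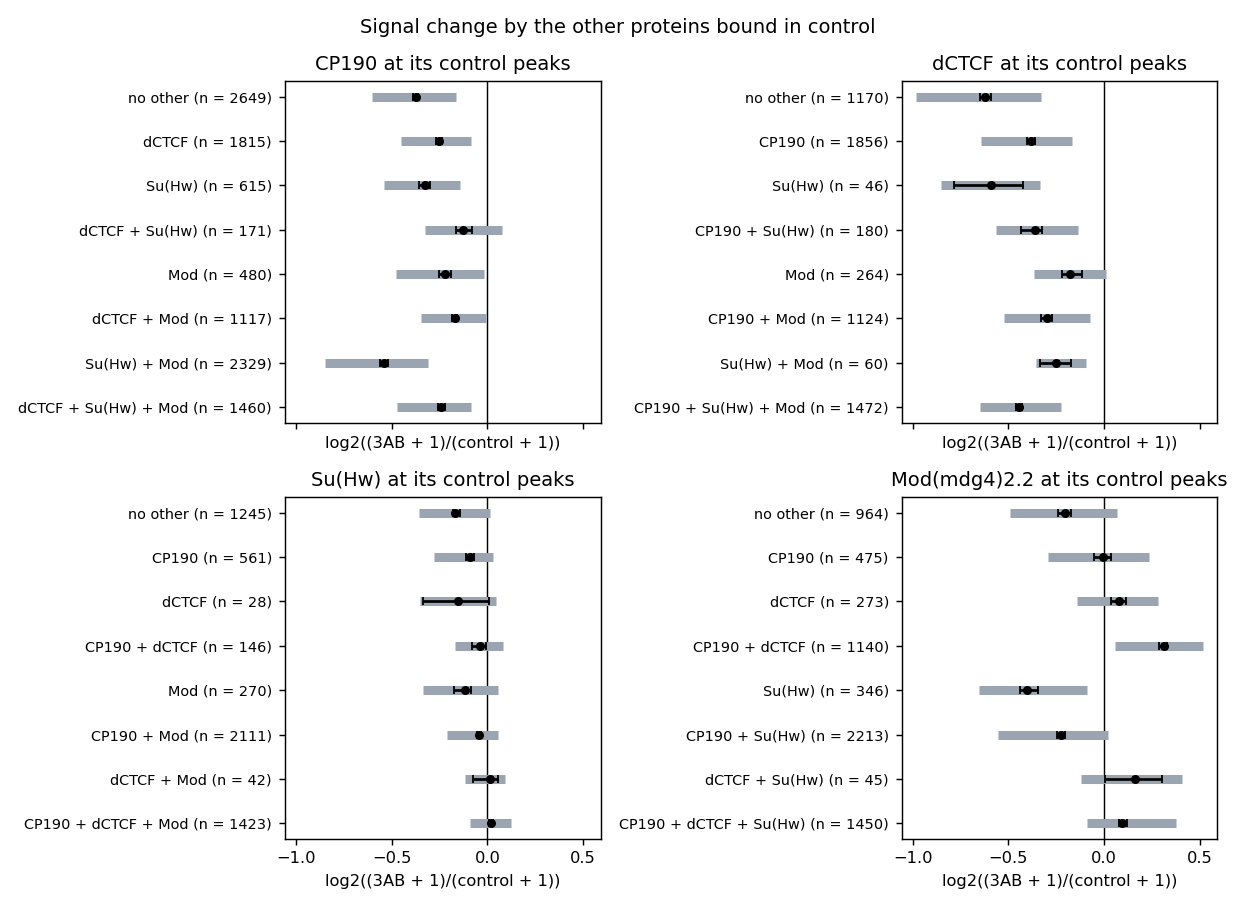
Median log2 change of each protein's signal (x axis, log2 of 3AB plus 1 over control plus 1) at its control peaks, grouped by which other proteins had an overlapping control peak (y axis, with the number of peaks; Mod stands for Mod(mdg4)2.2). Points are medians with 95% order-statistic intervals and grey bars span the quartiles; CP190 is lowest with Su(Hw) and Mod(mdg4)2.2 at −0.54, and Mod(mdg4)2.2 highest with CP190 and dCTCF at 0.31.

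Where 1 protein was strongly reduced, some partners were reduced with it. These joint changes were examined after the data had been seen. At the 48 Su(Hw) peaks with a log2 change of −1 or less, Mod(mdg4)2.2 had a median of −1.20 (−1.40 to −1.11) over the 42 with a control Mod(mdg4)2.2 peak, against −0.090 over all 3846 shared sites, and CP190 had −0.79 (−0.98 to −0.61) over the 43 with a control CP190 peak, against −0.30 over all 4241. At the 278 control Mod(mdg4)2.2 peaks that passed the same limit, CP190 had a median of −1.08 (−1.15 to −1.02) over 217, against −0.32 over all 5278, and Su(Hw) had −0.62 (−0.69 to −0.57) over 241, against −0.011 over all 4054. At the 830 control CP190 peaks with a change of −1 or less, Mod(mdg4)2.2 had a median of −0.55 (−0.62 to −0.48) over 561 shared sites, against 0.019 over all 5386. For dCTCF it was −0.69 (−0.78 to −0.60) over 152 shared sites, against −0.34 over all 4563. For Su(Hw) it was −0.066 (−0.10 to −0.032) over 532 shared sites, against −0.016 over all 4575. At the 557 control dCTCF peaks with such a change, CP190 had −0.42 (−0.46 to −0.35) over 265, against −0.19 over all 4632. Su(Hw) had −0.10 (−0.17 to −0.027) over 113, against 0.022 over all 1758, and Mod(mdg4)2.2 had −0.030 (−0.16 to 0.020) over 128, against 0.22 over all 2920. Across shared control sites, which are not independent replicates, the changes of CP190 and Mod(mdg4)2.2 correlated with a Pearson r of 0.631 (Spearman rho 0.664, 5386 sites), those of Su(Hw) and Mod(mdg4)2.2 with 0.602 (0.491, 3846 sites), and those of CP190 and dCTCF with 0.357 (0.312, 4563 sites). CP190 and Su(Hw) gave 0.237 (0.222, 4575 sites), dCTCF and Mod(mdg4)2.2 0.274 (0.219, 2920 sites), and dCTCF and Su(Hw) 0.251 (0.179, 1758 sites).

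The small chromosome arm 4 differed from the other arms for CP190. The median log2 change at its 65 CP190 regions was −0.80, against −0.31 to −0.26 on the other 5 arms, and 57.8% of its 64 control peaks were retained (45.6% to 69.1%). Outside peaks, the CP190 signal of arm 4 with 3AB was 0.849 times that of control, while it was 1.26 to 1.32 times on the other arms. For Mod(mdg4)2.2 the corresponding ratio on arm 4 was 0.812 against 0.984 to 1.03 elsewhere, with a median change of −0.16 at 30 regions. The background ratio on arm 4 was 1.32 for dCTCF, against 1.21 to 1.24 elsewhere, and 1.15 for Su(Hw), against 1.02 to 1.07. Arm 4 thus lay above the other arms for dCTCF and Su(Hw) and below them for CP190 and Mod(mdg4)2.2. The dCTCF median at its 40 regions on arm 4 was −0.39, against −0.36 on X and −0.22 to −0.17 on the other 4 arms, and the Su(Hw) median at 22 regions was −0.0028.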

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

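The tests of Su(Hw) loss, of the duplicate limit and of a common dilution were chosen after the result was seen, and that of the duplicate limit was redefined after its values were seen. The dropout test was prompted by named regions with signal near 0, its reading was set after the background windows had been examined, and the wording of the dCTCF pattern was set after its values were seen. The direction of the median log2 change differed between proteins, with −0.28 for CP190, −0.22 for dCTCF, −0.030 for Su(Hw) and 0.10 for Mod(mdg4)2.2, and this difference was not tested. At control peaks alone the medians were −0.32, −0.41, −0.047 and −0.037, so the difference in direction depended on including regions called with 3AB alone. The number of peaks with 3AB minus control was −1649 for CP190, 663 for dCTCF, −112 for Su(Hw) and 1063 for Mod(mdg4)2.2, which was not tested either. Outside the compared arms, Mod(mdg4)2.2 peaks on the mitochondrial genome held 96 tags in control and 169 with 3AB, which was not tested.

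The CP190 change was lower at sites with Su(Hw) and Mod(mdg4)2.2 but without dCTCF than at sites with dCTCF, with a difference of medians of −0.32 (−0.34 to −0.30). Relative to the flanking background it was −0.30 (−0.32 to −0.28), which argues against a regional library bias as the whole cause, and the Su(Hw) median at the first sites was −0.034 (−0.043 to −0.023), which argues against a loss of Su(Hw) from them. Of the 433 class members with a change of −1 or less, 6.0% lay under 0.5 times their flank with 3AB (4.13% to 8.65%), against 20.4% of background windows. That result had been set to exclude a dropout of fragments, but a graded dropout leaves bound sites above their flank, and the share of background windows was 13.2% in control, so dropout cannot be told apart from a change in binding. In widened regions the difference of medians was −0.24, with fragment lengths of 87 bp in control and 115 bp with 3AB. Widening adds flanking signal to each region and by itself shrinks such a difference. The smaller value therefore does not show whether fragment length plays a part. Base composition was not tested. Composition bias, a part played by fragment length, a difference between single libraries and an effect of 3AB stay open.

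The Mod(mdg4)2.2 change was higher at sites with CP190 and dCTCF but without Su(Hw) than at sites with CP190 and Su(Hw) but without dCTCF, with a difference of medians of 0.54 (0.51 to 0.56). It was 0.47 (0.44 to 0.50) relative to the flanking background, which argues against a regional bias as the whole cause, and 0.48 in widened regions, which argues against fragment length as the whole cause. Of the 192 members of the second class with a change of −1 or less, 0% lay under 0.5 times their flank with 3AB (up to 1.96%), against 11.9% of background windows with 3AB and 9.61% in control. For the same reason as for CP190, a graded dropout of fragments cannot be told apart from a change in binding. Base composition was not tested. A shift of Mod(mdg4)2.2 between these classes with 3AB is a hypothesis that was not tested, and it stays open beside a difference between single libraries.

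The dCTCF change was lower at sites without the other proteins than at sites with CP190, with a difference of medians of −0.24 (−0.27 to −0.20). Relative to the flanking background it was −0.22 (−0.26 to −0.18), which argues against a regional bias as the whole cause. One dilution of all sites would place the median of the first sites, −0.62, among random sets matched on signal, whose middle 95% ran from −0.43 to −0.38, and it lay at the 0th percentile. The first sites had a lower median highest bin in control (7.17 against 9.18) and lay at the 0th percentile of sets matched on that bin (−0.43 to −0.38), which argues against the lower duplicate limit with 3AB acting through tag density. The classes were drawn on control peaks, a choice that by itself favours lower values. Peaks without the other proteins lay at the 0th percentile of sets matched on signal for CP190, Su(Hw) and Mod(mdg4)2.2 too. In widened regions, where added flanking signal by itself shrinks a difference, it was −0.17, with fragment lengths of 98 bp in control and 91 bp with 3AB. Copies per position were not analysed here and base composition was not tested. Both stay open beside the choice of control peaks, a part played by fragment length, a difference between single libraries and an effect of 3AB.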

How the results depend on the processing

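Comparisons relative to the flanking background, in widened regions, without arm 4 and of the class differences were chosen after the result was seen. Over all results and alternatives, 51 values stayed within their interval, or within 1.5 times for counts, 140 moved beyond it and 4 changed sign. Counts from smaller sets of regions were compared without regard to the number of regions, so some moved through set size alone. The CP190 median changed sign without scaling, where the longer fragment length of the 3AB track raises its values, the Su(Hw) median with the highest bin, and the Mod(mdg4)2.2 median in the upper 50% of regions by mean signal and at control peaks alone. For the other values the cause was not tested. The CP190 median was negative under the other alternatives run and the dCTCF median under all alternatives run, and the class differences kept their sign under each alternative run. The 15 values computed without arm 4 stayed within these limits. With a 50% reciprocal overlap, the retained share was 72.9% (CP190), 62.7% (dCTCF), 88.1% (Su(Hw)) and 84.8% (Mod(mdg4)2.2), and the share of 3AB peaks also in control was 86.2% (CP190), 56.7% (dCTCF), 89.9% (Su(Hw)) and 73.5% (Mod(mdg4)2.2). With a 50% reciprocal overlap, the share with a CP190 peak in control was 57.0% (dCTCF), 40.9% (Su(Hw)) and 62.8% (Mod(mdg4)2.2), and the share with a CP190 peak with 3AB was 41.2% (dCTCF), 46.4% (Su(Hw)) and 60.4% (Mod(mdg4)2.2). With a 50% reciprocal overlap, the CP190 class medians were −0.21 (dCTCF), −0.39 (Su(Hw)), −0.40 (Mod(mdg4)2.2), −0.14 (dCTCF + Mod(mdg4)2.2), −0.57 (Su(Hw) + Mod(mdg4)2.2) and −0.21 (dCTCF + Su(Hw) + Mod(mdg4)2.2), and the retained CP190 shares by class were 90.9% (dCTCF), 69.6% (Su(Hw)), 95.6% (dCTCF + Su(Hw)), 81.4% (Su(Hw) + Mod(mdg4)2.2) and 98.8% (dCTCF + Su(Hw) + Mod(mdg4)2.2). With a 50% reciprocal overlap, the class difference was −0.38 (CP190) and −0.16 (dCTCF). With peak centres within 250 bp, the retained share was 71.4% (CP190), 65.0% (dCTCF), 85.1% (Su(Hw)) and 84.5% (Mod(mdg4)2.2), and the share of 3AB peaks also in control was 84.4% (CP190), 58.9% (dCTCF), 86.8% (Su(Hw)) and 73.2% (Mod(mdg4)2.2). In the upper 50% of each list, the retained share was 81.7% (CP190), 80.7% (dCTCF), 94.0% (Su(Hw)) and 91.3% (Mod(mdg4)2.2), and the share of 3AB peaks also in control was 97.1% (CP190), 75.3% (dCTCF), 96.2% (Su(Hw)) and 79.5% (Mod(mdg4)2.2). In the upper 50% of each list, the share with a CP190 peak in control was 63.2% (dCTCF), 61.4% (Su(Hw)) and 62.3% (Mod(mdg4)2.2), and the share with a CP190 peak with 3AB was 57.5% (dCTCF), 48.4% (Su(Hw)) and 54.3% (Mod(mdg4)2.2). With equal numbers of top peaks, the retained share was 87.9% (CP190), 67.1% (dCTCF), 90.3% (Su(Hw)) and 84.9% (Mod(mdg4)2.2), and the share of 3AB peaks also in control was 89.0% (CP190), 69.8% (dCTCF), 90.8% (Su(Hw)) and 84.0% (Mod(mdg4)2.2). Without scaling, the median was 0.046 (CP190), −0.32 (dCTCF), −0.12 (Su(Hw)) and 0.22 (Mod(mdg4)2.2). Without scaling, regions at −1 or less numbered 431 (CP190), and regions at 1 or more numbered 14 (CP190), 50 (dCTCF) and 185 (Mod(mdg4)2.2). With scaling outside all peaks, the median was −0.56 (CP190), −0.42 (dCTCF) and −0.075 (Su(Hw)). With scaling outside all peaks, regions at −1 or less numbered 1478 (CP190) and 1051 (dCTCF), and regions at 1 or more numbered 19 (dCTCF). With scaling outside all peaks, the CP190 class medians were −0.63 (no other), −0.55 (dCTCF), −0.57 (Su(Hw)), −0.41 (dCTCF + Su(Hw)), −0.47 (Mod(mdg4)2.2), −0.48 (dCTCF + Mod(mdg4)2.2), −0.80 (Su(Hw) + Mod(mdg4)2.2) and −0.57 (dCTCF + Su(Hw) + Mod(mdg4)2.2). With scaling outside all peaks, the class difference was −0.27 (CP190) and −0.20 (dCTCF). With a pseudocount of 0.25, the median was −0.33 (CP190), −0.28 (dCTCF) and 0.12 (Mod(mdg4)2.2). With a pseudocount of 0.25, regions at −1 or less numbered 1336 (CP190), 978 (dCTCF), 139 (Su(Hw)) and 470 (Mod(mdg4)2.2), and regions at 1 or more numbered 15 (CP190), 577 (dCTCF), 2 (Su(Hw)) and 382 (Mod(mdg4)2.2). With a pseudocount of 4, the median was −0.18 (CP190), −0.12 (dCTCF), −0.021 (Su(Hw)) and 0.066 (Mod(mdg4)2.2). With a pseudocount of 4, regions at −1 or less numbered 139 (CP190), 174 (dCTCF), 1 (Su(Hw)) and 44 (Mod(mdg4)2.2), and regions at 1 or more numbered 1 (dCTCF) and 1 (Mod(mdg4)2.2). With the highest bin, the median was −0.43 (CP190), −0.27 (dCTCF) and 0.0098 (Su(Hw)). With the highest bin, regions at −1 or less numbered 1823 (CP190), 1158 (dCTCF), 183 (Su(Hw)) and 550 (Mod(mdg4)2.2), and regions at 1 or more numbered 17 (CP190), 487 (dCTCF), 11 (Su(Hw)) and 635 (Mod(mdg4)2.2). In the upper 50% of regions by mean signal, the median was −0.39 (dCTCF), −0.014 (Su(Hw)) and −0.010 (Mod(mdg4)2.2). In the upper 50% of regions by mean signal, regions at −1 or less numbered 381 of 5447 (CP190), 11 of 3134 (Su(Hw)) and 166 of 4299 (Mod(mdg4)2.2). Regions at 1 or more numbered 2 of 4253 (dCTCF) and 29 of 4299 (Mod(mdg4)2.2). Over all regions, those at −1 or less numbered 784 of 10894 (CP190), 48 of 6268 (Su(Hw)) and 275 of 8597 (Mod(mdg4)2.2). The smaller counts thus rest at least in part on the smaller sets. At control peaks alone, the median was −0.32 (CP190), −0.41 (dCTCF), −0.047 (Su(Hw)) and −0.037 (Mod(mdg4)2.2). At control peaks alone, regions at 1 or more numbered 1 of 6172 (dCTCF) and 45 of 6906 (Mod(mdg4)2.2). Relative to the flanking background, the median was −0.43 (CP190) and −0.33 (dCTCF). Relative to the flanking background, the CP190 class medians were −0.53 (no other), −0.41 (dCTCF), −0.45 (Su(Hw)), −0.28 (dCTCF + Su(Hw)), −0.32 (Mod(mdg4)2.2), −0.29 (dCTCF + Mod(mdg4)2.2), −0.66 (Su(Hw) + Mod(mdg4)2.2) and −0.36 (dCTCF + Su(Hw) + Mod(mdg4)2.2). Relative to the flanking background, the class difference was 0.47 (Mod(mdg4)2.2). In widened regions, the median was −0.24 (CP190), −0.17 (dCTCF) and 0.079 (Mod(mdg4)2.2). In widened regions, the class difference was −0.24 (CP190), −0.17 (dCTCF) and 0.48 (Mod(mdg4)2.2). Counts of regions were not made relative to the flanking background or in widened regions. No paired analysis was possible because each condition has 1 library per protein. The gene lists, genomic locations and motif searches and their alternatives were not run, since a genome and annotation of the files' release were not used here.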

Other observations

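These values were examined after the data had been seen. At the 48 control Su(Hw) peaks with a log2 change of −1 or less, 31 of the 42 with a control Mod(mdg4)2.2 peak had a Mod(mdg4)2.2 change of that size, 13 of the 43 with a control CP190 peak had such a CP190 change, and 3 of the 5 with a control dCTCF peak such a dCTCF change. Of the 469 Su(Hw) peaks called with 3AB alone on the major arms, 71.9% overlapped a control CP190 peak, 67.6% a control dCTCF peak and 62.0% a control Mod(mdg4)2.2 peak. For the 615 control-only Su(Hw) peaks these shares were 40.8%, 27.5% and 39.8%, and for the 5211 retained ones 76.6%, 28.2% and 69.1%. Against retained peaks, only the dCTCF share was thus higher at peaks called with 3AB alone.

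On the heterochromatic sequences of arms 2L, 2R, 3L and 3R, the ratio of the scaled mean signal with 3AB to that in control ran from 1.08 to 1.16 for CP190, 1.39 to 1.5 for dCTCF, 1.26 to 1.29 for Su(Hw) and 0.878 to 0.931 for Mod(mdg4)2.2. On that of X it was 1.05 for CP190, 0.869 for dCTCF, 1.25 for Su(Hw) and 0.947 for Mod(mdg4)2.2. Scaling to the arm mean also moves signal outside peaks. Outside peaks on the major arms other than arm 4, the ratio ran from 1.26 to 1.32 for CP190 and 1.21 to 1.24 for dCTCF. It ran from 1.02 to 1.07 for Su(Hw) and 0.984 to 1.03 for Mod(mdg4)2.2. The CP190 ratios on heterochromatic sequences thus lay below its own background ratio. The 2 dCTCF peaks on the heterochromatic sequence of X held 1544 tags in control and 830 with 3AB. The Y sequence held next to no signal in any library and is left out. Peaks outside the major arms numbered, in control and with 3AB, 63 and 34 for CP190, 43 and 47 for dCTCF, 19 and 26 for Su(Hw) and 32 and 31 for Mod(mdg4)2.2.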
